A study of Mus musculus with 30 samples.

How the data were processed

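Total RNA of spleen and lymph node was measured on Affymetrix Mouse Gene ST arrays. The series holds 30 arrays from 15 mice, with 1 array per tissue and mouse. Per the labels, 3 mice were FVB/N controls, 6 were asymptomatic Tg26 mice and 6 were Tg26 mice with lymphoma. The labels give heterozygous animals on the FVB/N background and ages from 5 to 12 months for the whole series, with no age or sex per mouse. By the labels, batch A held mice 1 to 3 of each of the 3 states, and batch B held mice 4 to 6 of the asymptomatic and lymphoma states, so that batch B held no FVB/N mouse. Arrays were grouped by the state, tissue and mouse number in the title and description. The spleen array of lymphoma mouse 4 carried the disease status code that other arrays used for FVB/N, while its title and description said lymphoma, and it was kept as lymphoma.

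The deposited table holds log2 expression levels per probe set, normalized by the authors at probe level with frozen robust multiarray analysis (fRMA), per the series' design text. That text also names a linear model with empirical Bayes shrinkage, surrogate variables for unexplained heterogeneity and Benjamini-Hochberg adjustment. Software versions, the number of surrogate variables and the thresholds are not given there. The log2 scale was checked on the values, which ran from 2.07 to 14.43, with array medians between 6.67 and 6.89. Scanner files were not used here, so signal over background was not assessed per probe. Of 35557 probe sets in the table, 1 had no values and 35556 were used. In the platform annotation, 21789 of them had 1 gene symbol, 1621 had several and 12146 were not listed. Of the probe sets with 1 symbol, 21698 matched a RefSeq gene by Entrez identifier (GRCm38.p6, used for current symbols and for which genes neighbour each other). Genes were named only from probe sets with 1 symbol. The 999 genes with more than 1 probe set (2850 probe sets) were represented by the probe set with the highest mean level, which left 19938 genes. No gene was filtered out.

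Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). All 30 arrays entered 1 fit with 6 groups and 6 surrogate variables. The surrogate variables were computed in R with an iteratively re-weighted algorithm (5 iterations, group structure protected), and their number came from 20 permutations of the residuals at a p limit of 0.1. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes of its comparison. Differences, standard errors (SE) and adjusted p are those of this fit unless a mean difference of the measured levels is named. Levels per group are means ± SD of the deposited log2 values. The comparisons were lymphoma against asymptomatic, asymptomatic against FVB/N and lymphoma against FVB/N in each tissue, and the difference between lymph node and spleen in the lymphoma against asymptomatic change.

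Gene lists, comparisons, tests, the rule for named genes and the other settings to be tried were fixed before the data were examined. There were 30 lists with 708 entries, of which 620 were measured. A salivary gland list was added after the data had been seen. Each list was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation. For lymphoma against asymptomatic, the named genes were the 12 largest rises and the 12 largest falls in each tissue among those with adjusted p under 0.05 and the same sign of the mean difference in both batches. Predicted and clone-named genes, small RNA genes and receptor variable segments were left out. For the other comparisons the 5 largest rises and falls were taken, and for each list up to 4 members with the smallest adjusted p, plus any member needed to describe a list that did not pass. Genes given without a value only complete a count and were chosen after their values were seen.

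Immunoglobulin variable segments were compared between the tissues of each mouse, since a B cell clone carries its own segments. For 12 probe sets whose symbols were all variable segments, each array's deviation from its group mean was correlated across probe sets between every spleen and every lymph node of the 6 lymphoma mice. The mean of the same-mouse correlations minus that of the others was tested with an exact two-sided permutation test over all 720 pairings.

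The fit was tested on data simulated from the real gene means, surrogate-variable effects and each gene's residual SD. Each known change was given to 66 or 67 genes. Of genes changed by 1 log2 unit it recovered 91% in spleen and 89.6% in lymph node, for lymphoma against asymptomatic and for asymptomatic against FVB/N. For lymphoma against FVB/N it recovered 79.1% and 77.6%, and for the difference between tissues 76.1%. At a change of 0.5, recovery lay between 16.4% (lymphoma against FVB/N) and 43.3% (asymptomatic against FVB/N), both in spleen. False calls were 11 of 158 in spleen and 9 of 148 in lymph node for lymphoma against asymptomatic, and 4 to 8 elsewhere. With few genes changed and 1 SD for all groups, these rates may not hold in the real data.

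Spleen and lymph node arrays of 1 mouse share an animal by the labels. Their deviations from the mean of their group and batch correlated at 0.484 on average in lymphoma mice (range 0.21 to 0.597, 6 of 6 over 0.1), at 0.067 in asymptomatic mice and at 0.011 in FVB/N mice. The nearest other array was that of the same mouse for 8 of 12 lymphoma arrays, 0 of 12 asymptomatic arrays and 0 of 6 FVB/N arrays. Same-numbered asymptomatic and FVB/N mice correlated over 0.1 in 3 of 3 pairs per tissue, with means of 0.154 in spleen and 0.352 in node. For these, blocked values are given where results change. Whether numbers pair mice stays open. Labels give no pairs, different numbers were not compared, number 1 gave 0.756 in node, and same-numbered lymphoma and FVB/N spleens averaged 0.141. Alternative settings, including each mouse left out in turn, are listed below.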

Results

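Gene expression was measured in spleen and lymph node to find genes and pathways that go with B cell lymphoma in Tg26 mice, which carry an HIV-1 provirus that makes no infectious virus. Compared were 3 FVB/N mice (background strain), 6 asymptomatic Tg26 mice and 6 with lymphoma.

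Several lymph node arrays carried transcripts of neighbouring organs. A salivary gland list, chosen after the data were seen, averaged 12.10 and 9.89 on the log2 scale in the nodes of FVB/N mice 2 and 3. It averaged 8.09 and 9.59 in those of asymptomatic mice 2 and 3 and 6.97 in that of lymphoma mouse 5, against 5.00 to 5.55 on the other arrays. Exocrine pancreas genes averaged 11.86 and 13.26 in the nodes of asymptomatic mice 5 and 6, and 7.33 and 8.31 in the spleens of asymptomatic mice 4 and 5, against 5.83 to 6.74 elsewhere. The adipose and muscle list averaged 7.84, 9.67, 9.44 and 8.75 in the nodes of asymptomatic mice 2 to 5 and 8.58 in that of FVB/N mouse 2, and 6.03 to 6.65 elsewhere.

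**Figure D1:**
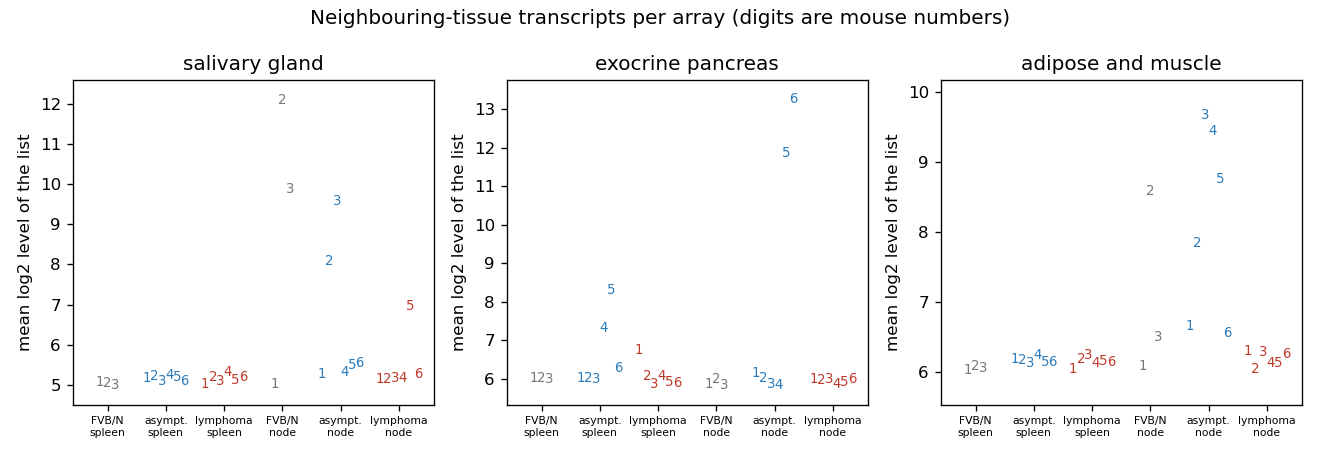
Mean log2 level of the salivary gland, exocrine pancreas, and adipose and muscle lists on each array, with each digit standing for 1 mouse in its group.

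With lymphoma, genes of early B cell development rose in spleen while those of T cells fell. Rag1, which recombines antigen receptor genes, went from 5.64 ± 0.14 in asymptomatic spleens to 10.65 ± 0.61 in spleens with lymphoma (SD, n = 6 each) and was at 6.08 ± 0.15 (SD, n = 3) in FVB/N spleens. The fitted rise was 4.83 on the log2 scale (SE 0.38, adjusted p = 6.02e-09). Igll1, part of the surrogate light chain of B cell precursors, rose by 4.76 (SE 0.35, adjusted p = 2.96e-09), and Vpreb3, another precursor gene, by 2.74 (SE 0.17, adjusted p = 4.23e-10). Cd3g, a chain of the T cell receptor complex, went from 10.98 ± 0.21 to 6.85 ± 1.03 (SD, n = 6 each), a fitted difference of -3.30 (SE 0.42, adjusted p = 4.25e-06). The CD8 chains Cd8a and Cd8b1 differed by -2.75 and -2.93 (SE up to 0.26, adjusted p up to 2.93e-08), and the T cell genes Ms4a4b and Trat1 by -3.62 and -2.89 (SE up to 0.35, adjusted p up to 5.11e-07). Dapl1 fell by 4.63 (SE 0.34, adjusted p = 3.04e-09) and Sidt1 by 2.98 (SE 0.26, adjusted p = 3.04e-08). In all, 3156 of 19938 genes changed in spleen (limma), 1710 of them higher and 1446 lower, and 834 by at least 1 log2 unit. The count was 4008 with batch as a term in place of surrogate variables, and 2769 and 1678 within batches A and B. Without lymphoma mouse 5 it was 5087.

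**Figure D2:**
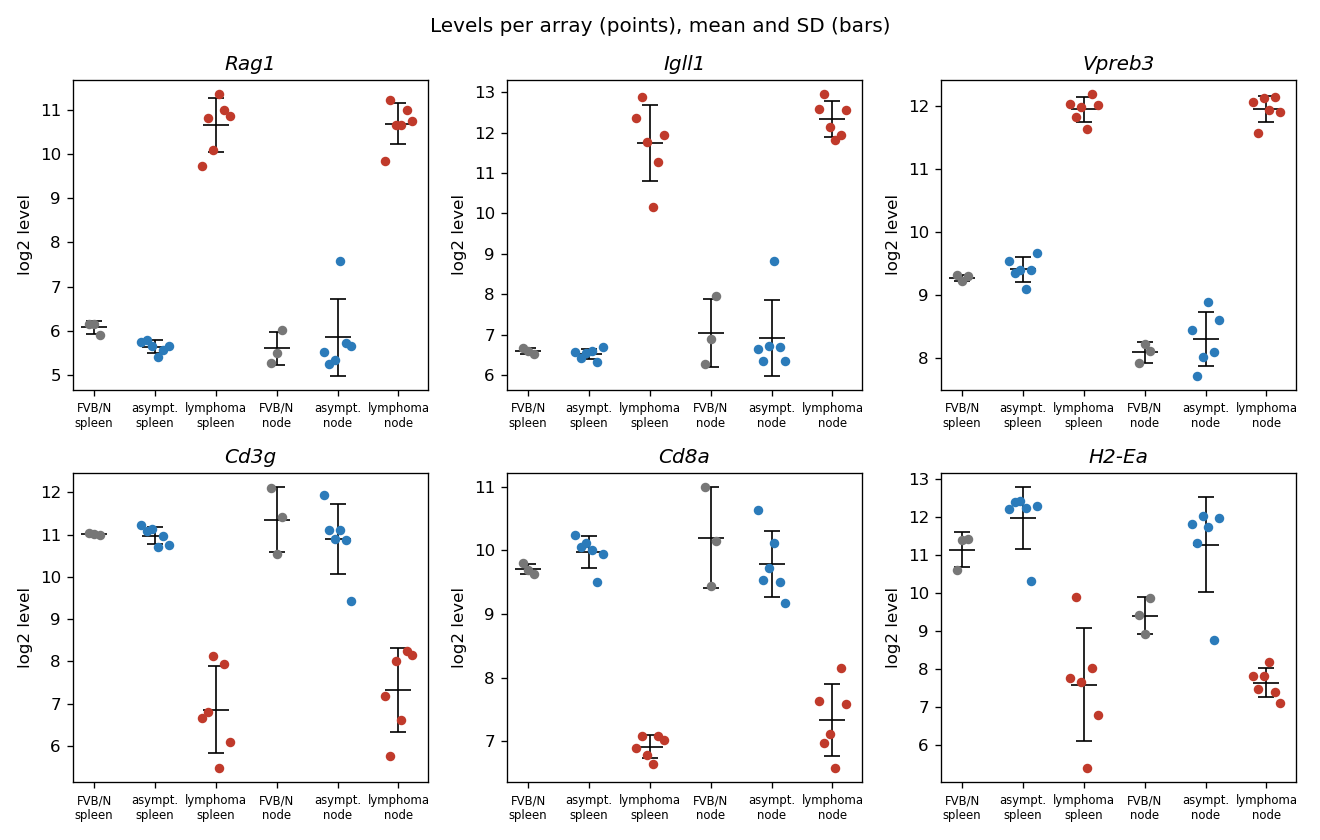
Log2 levels of Rag1, Igll1, Vpreb3, Cd3g, Cd8a and H2-Ea by group, with each point 1 array and bars for the mean and SD.

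Of 18 measured early B precursor genes, 13 rose and 2 (Flt3 and Lef1) fell in spleen, the same counts as adjusted over the list alone, with a median log2 difference of 1.5. The list rose as a group (camera adjusted p = 9.35e-15, and adjusted p = 0.00261 with an estimated correlation). Its transcription factors Myb and Sox4 rose by 3.02 and 2.55, and Cd93, a surface marker of precursors, by 3.51 (SE up to 0.21, adjusted p up to 1.23e-09). Of 38 proliferation genes, 36 rose (37 adjusted over the list alone), with a median of 1.57 and camera adjusted p = 2.43e-44, or adjusted p = 0.0313 with an estimated correlation. The mitotic genes Bub1b, Ccnb2, Aurkb and Cdc20 rose by 2.38, 2.07, 1.68 and 1.5 (SE up to 0.21, adjusted p up to 2.28e-07). Of 22 T lineage genes, 20 fell (21 adjusted over the list alone), with a median of -2.30 and camera adjusted p = 1.01e-29, or adjusted p = 0.00775 with an estimated correlation. Themis, Cd3d and Thy1 differed by -2.72, -2.72 and -2.17 (SE up to 0.23, adjusted p up to 2.69e-08).

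MHC class II genes fell too. H2-Ea, a class II chain outside the list, went from 11.98 ± 0.82 to 7.58 ± 1.49 (SD, n = 6 each), a fitted difference of -3.65 (SE 0.59, adjusted p = 8.94e-05). Of 14 genes, 9 fell and Ctse rose (11 and 1 adjusted over the list alone), with camera adjusted p = 3.83e-06, or adjusted p = 0.0399 with an estimated correlation. Ciita, the master regulator of class II genes, Cd40, H2-DMa and H2-Aa differed by -1.62, -1.38, -1.40 and -1.32 (SE up to 0.23, adjusted p up to 0.000269). Without lymphoma mouse 5, Ciita, H2-DMa and H2-Aa differed by -2.86, -2.20 and -2.16. Of 21 cytotoxic and NK genes, 12 fell and 1 (Klrb1c) rose (16 and 1 adjusted over the list alone). Camera gave adjusted p = 2.28e-09, but 0.0523 with an estimated correlation. The protease gene Ctsw, the NK receptor gene Ncr1 and the transcription factors Tbx21 and Eomes differed by -2.09, -2.08, -1.29 and -1.33 (SE up to 0.23, adjusted p up to 4.25e-06). Of 24 NF-kB targets, 10 fell (11 adjusted over the list alone), with camera adjusted p = 1.41e-06, but 0.0925 with an estimated correlation. Traf1, Nfkb2 and Tnip1 differed by -1.45, -0.85 and -0.64 (SE up to 0.18, adjusted p up to 3.53e-05), and Nfkb2 by -0.56 without lymphoma mouse 5 and -0.54 without lymphoma mouse 3. Of 20 dendritic cell genes, 10 fell and 1 (Tcf4) rose (14 and 1 adjusted over the list alone), with camera adjusted p = 1.41e-06, but adjusted p = 0.0925 with an estimated correlation. Clec9a, a receptor of cross-presenting dendritic cells, Ly6d, Fscn1 and Flt3 differed by -1.61, -1.73, -1.70 and -0.95 (SE up to 0.29, adjusted p up to 0.000272).

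By camera, 4 further lists moved in spleen. Of 28 Myc and ribosome biogenesis genes, 5 rose, namely Cad, Cdk4, Nop16, Pa2g4 and Wdr12 (6 adjusted over the list alone), with camera adjusted p = 8.25e-06, but adjusted p = 0.353 with an estimated correlation. Wdr12, Cdk4 and Pa2g4 rose by 0.59, 0.49 and 0.61 (SE up to 0.16, adjusted p up to 0.0105). Of 19 erythroid genes, 3 rose (4 with Kel adjusted over the list alone), with camera adjusted p = 8.62e-05, but adjusted p = 0.553 with an estimated correlation. Among them the transferrin receptor gene Tfrc rose by 2.08 (SE 0.26, adjusted p = 3.35e-06), Car2 by 1.13 (SE 0.37, adjusted p = 0.0393) and Rhag by 2.20 (SE 0.73, adjusted p = 0.0427). Of 20 adipose and muscle genes, 3 fell, namely Adipoq, Cidea and Plin1 (5 with Cidec and Pck1 adjusted over the list alone), with camera adjusted p = 0.000536, but adjusted p = 0.374 with an estimated correlation. Plin1, a fat droplet coat gene, differed by -1.19 (SE 0.36, adjusted p = 0.0245). Of 27 macrophage genes, 2 fell, Hmox1 by 1.32 (SE 0.35, adjusted p = 0.0117) and Msr1 by 0.98 (SE 0.31, adjusted p = 0.0304) (Hmox1 alone when adjusted over the list alone). Camera gave adjusted p = 0.0134, but 0.731 with an estimated correlation. The lists did not pass without asymptomatic mouse 4 (macrophage 0.249) or 6 (adipose 0.1), or without lymphoma mouse 1 (macrophage 0.0902), 2 (Myc 0.0723) or 5 (erythroid 0.363, adipose 0.197). Without lymphoma mouse 2, Wdr12, Cdk4 and Pa2g4 had adjusted p = 0.0676, 0.181 and 0.137, and Pa2g4 had 0.0557 without lymphoma mouse 1, while without lymphoma mouse 5 Cdk4 and Pa2g4 rose by 0.80 and 1.08. Hmox1 had adjusted p = 0.065 and Msr1 0.0862 without asymptomatic mouse 4, and Msr1 0.0593 without lymphoma mouse 1. Car2 did not pass without asymptomatic mouse 2 or 3 or lymphoma mouse 1, 2, 3 or 5, with adjusted p up to 0.749, and rose by 1.79 without asymptomatic mouse 4. Rhag did not pass without asymptomatic mouse 1, 2, 3, 5 or 6 or lymphoma mouse 1, 2, 3 or 5 (up to 0.484), nor Plin1 without asymptomatic mouse 1, 2, 4 or 6 or lymphoma mouse 1 or 5 (up to 0.254). Without surrogate variables the erythroid list (adjusted p = 0.395) and the adipose and muscle list (0.893) did not pass, and the macrophage median turned to 0.22 in batch A (0.843).

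No other list passed in spleen. Of 23 B lineage genes, 8 fell and Pou2af1 and Vpreb3 rose (10 fell and 4 rose, with Ebf1 and Cd37, adjusted over the list alone), with camera adjusted p = 0.0856. Among these, Cr2, the complement receptor of mature B cells, the homing receptor gene Cxcr5 and the IgM receptor gene Fcmr differed by -2.83, -1.91 and -1.38 (SE up to 0.33, adjusted p up to 9.88e-05), and Fcmr by -3.23 without lymphoma mouse 5 and -2.48 without lymphoma mouse 3. Of 19 B-1 and marginal zone genes, Plac8 and Sox4 rose and 6 fell (3 with Bhlhe41 and 6 adjusted over the list alone, camera adjusted p = 0.0856). Of 16 germinal centre genes, Elk3 and Stmn1 rose and Basp1, Efnb1, Fas, Gcsam and Rgs13 fell (2 and 6 adjusted over the list alone, adjusted p = 0.418). Of 23 plasma cell genes, Mzb1, Prdm1 and Sdc1 rose and Cd28 and Tnfrsf13b fell (5 with Derl3 and Creld2, and 2, adjusted over the list alone, adjusted p = 0.519). Of 18 T exhaustion and regulatory T genes, Cd160, Cd244a and Il2ra rose and Ikzf2, Nrp1, Tnfrsf18, Tnfrsf9 and Tox fell (5 with Entpd1 and Il10, and 9, adjusted over the list alone, adjusted p = 0.388). Cd244a rose by 2.16 (SE 0.17, adjusted p = 6.78e-09), or by 1.28 without lymphoma mouse 5. Of 22 apoptosis and p53 genes, Bak1 and Cdkn2c rose and the death receptor gene Fas and the survival gene Bcl2 fell (the same adjusted over the list alone, adjusted p = 0.789). Fas and Bcl2 differed by -1.48 and -1.05 (SE up to 0.15, adjusted p up to 2.38e-05), and Fas by -0.92 without lymphoma mouse 5 and -0.98 without lymphoma mouse 3. Of 23 endothelium genes, Egfl7 and Eng rose and Esam fell (the same adjusted over the list alone, adjusted p = 0.23), with Eng at 2.60 (SE 0.28, adjusted p = 5.46e-07). Of 30 inflammatory genes, Tgfb1 rose and 6 fell (1 and 7 adjusted over the list alone, adjusted p = 0.11). Of 28 interferon response genes, Cxcl9, Ddx58 and Zbp1 fell (the same adjusted over the list alone, adjusted p = 0.174).

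In spleen, the follicular dendritic cell genes Cr2 and Fcer2a fell (12 measured, adjusted p = 0.636), as did Thy1 of 26 stroma genes (0.15), Tapbp of 14 MHC class I genes (0.132), Sdha of 34 oxidative phosphorylation genes (0.362) and Aldoa, Hif1a and Slc2a1 of 22 glycolysis and hypoxia genes (0.613), with the same counts adjusted over the list alone. Gp5 rose among 15 megakaryocyte genes (adjusted p = 0.974, the same adjusted over the list alone). Mmp9 rose among 21 neutrophil genes (0.519), but 0 passed adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. None of 16 exocrine pancreas genes passed (adjusted p = 0.737, with 1 at an unadjusted p under 0.05), nor any of 3 immunoglobulin constant region genes (0.84, with 0). The medians of the fitted and the measured differences had opposite signs for the plasma cell (0.05 and -0.04), neutrophil (0.15 and -0.02), apoptosis (0.05 and -0.02), oxidative phosphorylation (-0.11 and 0.27) and glycolysis (-0.12 and 0.05) lists.

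Other large rises in spleen were Drc7, a cilium gene, at 4.81 (SE 0.30, adjusted p = 4.23e-10), Gas2l3, Ptgr1 and Tmem255a at 3.90, 3.86 and 3.8 (SE up to 0.35, adjusted p up to 5.63e-08), and Cdhr2 at 3.73 (SE 0.51, adjusted p = 1.12e-05). Of 4 sex-linked genes, Xist had 5.47 (SE 1.11, adjusted p = 0.00106), though high only in lymphoma mice 3 and 5 (11.37 and 11.06) and at -0.05 without them, and Eif2s3y, Kdm5d and Uty differed by -4.87, -3.39 and -3.11 (SE up to 0.89, adjusted p up to 0.00106), the same adjusted over the list alone, while the list did not pass (camera adjusted p = 0.0722). The growth factor gene Igf2 had 5.03 (SE 0.88, adjusted p = 0.000249), Il1r2 3.78 (SE 0.46, adjusted p = 2.76e-06), Lhfpl1 3.60 (SE 0.46, adjusted p = 4.71e-06) and Scin 3.56 (SE 0.56, adjusted p = 6.66e-05). The measured means differed by 1.93 for Xist, 2.56 for Igf2, 1.95 for Il1r2 and 1.44 for Scin, and without surrogate variables none of these 4, nor Eif2s3y, Kdm5d or Uty, passed. Without lymphoma mouse 5, Xist had 1.60 (adjusted p = 0.221), Igf2 0.58, Il1r2 0.44, Scin 0.47, Eif2s3y -1.25, Kdm5d -1.23 and Uty -0.83 (0.112 to 0.506), and Lhfpl1 1.33. Without lymphoma mouse 3 the values were 2.40 for Xist, 1.54 (adjusted p = 0.186) for Igf2, 1.34 for Il1r2, 1.73 for Lhfpl1, 1.15 for Scin, -2.08 for Eif2s3y, -1.67 for Kdm5d and -1.14 for Uty. Without lymphoma mouse 2, Igf2 had 3.09 and Il1r2 2.28, and without lymphoma mouse 4 Scin had 2.28.

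In lymph node, lymphoma also went with higher Igll1, Rag1 and Vpreb3 and lower Cd3g. Igll1 rose by 5.24 (SE 0.39, adjusted p = 1.9e-09), from 6.93 ± 0.94 to 12.33 ± 0.44 (SD, n = 6 each), against 7.05 ± 0.84 (SD, n = 3) in FVB/N nodes. Rag1 rose by 4.44 and Vpreb3 by 3.86 (SE up to 0.42, adjusted p up to 4.53e-08). Cd3g went from 10.90 ± 0.82 to 7.33 ± 0.99 (SD, n = 6 each), a fitted difference of -3.92 (SE 0.46, adjusted p = 9.91e-07). Tek, the receptor of angiopoietins on vessel walls, differed by -1.42 (SE 0.20, adjusted p = 9.37e-06) and the stromal chemokine gene Ccl19 by -2.0 (SE 0.37, adjusted p = 0.000257). In all, 4800 of 19938 genes changed in lymph node (limma), 2317 higher and 2483 lower, and 1521 by at least 1 log2 unit. The count was 6537 with batch as a term, 3319 and 4015 within batches A and B, and 3184 without asymptomatic mouse 4. It was 2966 with batch and the 3 neighbouring-tissue lists as covariates in place of surrogate variables. Without asymptomatic mouse 4, Tek differed by -0.93.

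Of 18 early B precursor genes, 12 rose and 2 (Flt3 and Lef1) fell in lymph node (12 and 3, with Arpp21, adjusted over the list alone), with a median of 1.95 and camera adjusted p = 8.89e-11, or adjusted p = 0.00911 with an estimated correlation. Cd93, Myb and Cd24a rose by 3.64, 3.42 and 2.45 (SE up to 0.23, adjusted p up to 1.28e-08). All 38 proliferation genes rose, also adjusted over the list alone, with a median of 2.20 and camera adjusted p = 2.85e-41, or adjusted p = 0.0409 with an estimated correlation. Ccnb2, Aurkb, Gins1 and Cdc20, genes of mitosis and replication, rose by 2.88, 2.50, 2.35 and 1.95 (SE up to 0.20, adjusted p up to 1.22e-08). Of 22 T lineage genes, 21 fell (22 adjusted over the list alone), with a median of -2.95 and camera adjusted p = 1e-28, or adjusted p = 0.00911 with an estimated correlation. Cd3d, Themis, Bcl11b and Thy1 differed by -3.38, -3.23, -2.95 and -2.81, and Trat1 and, outside the list, Prkcq and Ms4a4b by -3.52, -3.35 and -3.99 (SE of the 7 genes up to 0.39, adjusted p up to 6.83e-08). Dapl1 fell by 4.64 (SE 0.38, adjusted p = 6.85e-09). Of 21 cytotoxic and NK genes, 11 fell (12 adjusted over the list alone, camera adjusted p = 5.59e-09, but 0.0782 with an estimated correlation). Ctsw, the pore-forming protein gene Prf1, Il2rb and Ccl5 differed by -2.65, -1.57, -2.04 and -2.60 (SE up to 0.31, adjusted p up to 1.25e-06).

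Of 23 endothelium genes, 17 fell and 1 (Eng) rose in lymph node (18 and 1 adjusted over the list alone), with camera adjusted p = 5.59e-09, but adjusted p = 0.204 with an estimated correlation. Tie1, Cdh5 and Cldn5, which belong to vessel signalling and junctions, differed by -1.23, -1.88 and -1.27 (SE up to 0.31, adjusted p up to 0.000115). Of 26 stroma and extracellular matrix genes, 9 fell (10 adjusted over the list alone), with camera adjusted p = 2.22e-05, but adjusted p = 0.311 with an estimated correlation, and Lum differed by -1.77 (SE 0.33, adjusted p = 0.000317). Of 20 adipose and muscle genes, 11 fell, also adjusted over the list alone, with camera adjusted p = 7.65e-06, but adjusted p = 0.204 with an estimated correlation. The brown fat gene Ucp1, Fabp4, Pck1, Cidec and, outside the list, Car3 differed by -3.63, -3.55, -2.90, -2.35 and -3.33 (SE up to 0.65, adjusted p up to 0.00028). Of 27 macrophage genes, 7 fell, also adjusted over the list alone, with camera adjusted p = 0.00691, but 0.504 with an estimated correlation. The sinus and marginal macrophage genes Timd4, Marco, Siglec1 and, outside the list, Cd209b differed by -2.19, -1.82, -1.99 and -3.45 (SE up to 0.55, adjusted p up to 0.000814). With neighbouring-tissue covariates Car3 did not pass (adjusted p = 0.0916), while the adipose and muscle list and its members cannot be tested so, since the list is 1 of the covariates. Without arrays with such tissue, the macrophage list, Car3, Pck1, Cidec, Cd209b, Timd4, Marco, Ccl19, Tie1, Cdh5 and Cldn5 did not pass (adjusted p from 0.0741 to 0.905). That rests on 1 asymptomatic node, which was the lowest in macrophage genes (7.62, next 9.31), and on the spread of other groups, so it decides little. Without asymptomatic mouse 4 the stroma (adjusted p = 0.0623) and macrophage (0.427) lists did not pass, and Marco and Siglec1 differed by -1.13 and -1.30. The macrophage list did not pass without asymptomatic mouse 2 (0.18) or lymphoma mouse 3 (0.0552), and without asymptomatic mouse 1 Pck1 and Cidec differed by -4.40 and -3.67.

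Of 24 NF-kB targets, 17 fell, also adjusted over the list alone, with camera adjusted p = 2.27e-07, but 0.0936 with an estimated correlation. Traf1, Tnip1 and Relb differed by -2.04, -1.14 and -0.96 (SE up to 0.20, adjusted p up to 8.6e-05). Of 20 dendritic cell genes, 12 fell and 1 (Tcf4) rose (13, and 2 with Clec4a4, adjusted over the list alone), with camera adjusted p = 2.22e-05, but adjusted p = 0.162 with an estimated correlation. Fscn1, the chemokine gene Ccl22 and Itgae differed by -3.43, -2.50 and -2.15, and Tcf4 rose by 1.37 (SE up to 0.32, adjusted p up to 5.67e-06). Of 14 MHC class II genes, 9 fell and 1 (Ctse) rose, also adjusted over the list alone, with camera adjusted p = 0.000585, but adjusted p = 0.15 with an estimated correlation. H2-Eb1, Ciita, Cd74 and, outside the list, H2-Ea differed by -2.96, -1.18, -0.88 and -3.81 (SE up to 0.65, adjusted p up to 0.000544). Of 18 T exhaustion and regulatory T genes, 10 fell and 2 (Cd244a and Entpd1) rose (12 and 2 adjusted over the list alone), with camera adjusted p = 0.000585, but adjusted p = 0.304 with an estimated correlation. Tnfrsf18 and Tox differed by -1.48 and -2.03, and Cd244a rose by 2.75 (SE up to 0.26, adjusted p up to 4.01e-06). Of 30 inflammatory genes, 9 fell and 1 (Tgfb1) rose (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00317, but adjusted p = 0.268 with an estimated correlation. Cxcl10 and Il15 differed by -1.5 and -1.97 (SE up to 0.25, adjusted p up to 6.3e-06). With only the 1 asymptomatic node free of such tissue, the inflammatory list (adjusted p = 0.0572), Il15 (0.137) and Relb (0.0944) did not pass. Cd74 did not pass without asymptomatic mouse 4 (0.0735) or 1 (0.0514) and differed by -1.39 and -1.40 without lymphoma mouse 5 and 3, while Ciita differed by -0.78, -1.93 and -2.0 without asymptomatic mouse 1 and lymphoma mice 5 and 3.

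Of 21 neutrophil genes, 10 rose in lymph node (14 adjusted over the list alone), with camera adjusted p = 4.62e-06, but adjusted p = 0.304 with an estimated correlation and adjusted p = 0.0594 without surrogate variables. The granule genes Lcn2, Ngp, Chil3 and Mmp9 rose by 3.41, 3.30, 3.02 and 2.62 (SE up to 0.75, adjusted p up to 0.00209). Of 19 erythroid genes, 7 rose, also adjusted over the list alone, with camera adjusted p = 6.13e-05, but 0.388 with an estimated correlation. Tfrc and Car2 rose by 2.40 and 3.25 (SE up to 0.41, adjusted p up to 2.53e-06). Of 28 Myc and ribosome biogenesis genes, 13 rose (16 adjusted over the list alone), with camera adjusted p = 7.65e-06, but adjusted p = 0.29 with an estimated correlation, and Wdr12 and Nop58 rose by 0.74 and 0.68 (SE up to 0.16, adjusted p up to 0.0017). Of 23 B lineage genes, 8 rose and 6 fell (10 and 6 adjusted over the list alone), with camera adjusted p = 0.0208 upward, but adjusted p = 0.441 with an estimated correlation. The receptor pathway genes Blnk and Cd79b and the coactivator gene Pou2af1 rose by 1.62, 1.10 and 1.48 (SE up to 0.15, adjusted p up to 5.11e-07), while Btla, Cr2, Cxcr5, Fcer2a, Fcmr and Ms4a1 fell. Of 23 plasma cell genes, Mzb1, Sdc1, Sdf2l1 and Xbp1 rose and Cd28 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.00847, but adjusted p = 0.304 with an estimated correlation. Mzb1 rose by 2.65 (SE 0.21, adjusted p = 3.06e-09) and Sdc1 by 1.31 (SE 0.31, adjusted p = 0.00266). The median measured difference had the opposite sign to the fitted one for the erythroid (-0.39 and 1.09), B lineage (-0.19 and 0.40) and plasma cell (-0.03 and 0.52) lists, and none of the 3 passed without surrogate variables (adjusted p = 0.596, 0.742 and 0.706). The B lineage list did not pass without asymptomatic mouse 6 (0.151) or lymphoma mouse 3, 4 or 5 (0.282, 0.147 and 0.246), with its median at -0.04, 0.08 and 0.08 without the last 3, nor the plasma cell list without asymptomatic mouse 1 or 6 or lymphoma mouse 3 or 5 (0.057 to 0.131). Sdc1 did not pass without lymphoma mouse 3, 4, 5 or 6 (to 0.526), nor Ngp without lymphoma mouse 1 (0.0587), Wdr12 without lymphoma mouse 1 (0.0951) or Nop58 without asymptomatic mouse 1 (0.147). Mmp9 rose by 1.66 and 1.57 without lymphoma mouse 5 and 3.

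In lymph node, 3 of 14 MHC class I genes fell, namely Nlrc5, Psmb10 and Tapbp, also adjusted over the list alone, with camera adjusted p = 0.0408, but adjusted p = 0.441 with an estimated correlation. Tapbp and Psmb10 differed by -0.75 and -0.56 (SE up to 0.18, adjusted p up to 0.0215). Of 34 oxidative phosphorylation genes, Cox7b, Ndufa8 and Sdha fell (Sdha alone when adjusted over the list alone), with camera adjusted p = 0.0305, but adjusted p = 0.513 with an estimated correlation. Sdha, of complex II, differed by -0.72 (SE 0.13, adjusted p = 0.000249). The MHC class I list did not pass without any 1 of lymphoma mice 1 to 6 or asymptomatic mice 1, 2, 3 and 6 (adjusted p from 0.057 to 0.765), and Psmb10 did not without asymptomatic mouse 2 or 6 or lymphoma mouse 1, 3, 4 or 5 (up to 0.201) and differed by -0.89 without asymptomatic mouse 4. The oxidative phosphorylation list did not pass without asymptomatic mouse 3, 5 or 6 or lymphoma mouse 3, 4 or 5 (0.077 to 0.336), and its median turned positive at 0.08, 0.03 and 0.06 without asymptomatic mouse 6 and lymphoma mice 3 and 5. It was higher with neighbouring-tissue covariates, at 0.56 (adjusted p = 5.13e-10), and without arrays with such tissue (1 asymptomatic node, spread from other groups), at 0.18 (0.00798). Sdha did not pass without asymptomatic mouse 4 (0.0563) or lymphoma mouse 5 (-0.36, 0.107), and differed by -0.40 and -0.47 without asymptomatic mouse 6 and lymphoma mouse 3. The other 10 lists did not pass in lymph node as groups, with camera adjusted p from 0.134 to 0.43. Fitted and measured medians had opposite signs for the megakaryocyte (0.18 and -0.35), pancreas (0.31 and -2.24), interferon (-0.15 and 0.16) and immunoglobulin (0.31 and -0.95) lists. Among their members, Fas and Bcl2 differed by -1.84 and -1.65 (SE up to 0.17, adjusted p up to 1.24e-07).

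Other large rises in lymph node were Drc7 at 5.07, Adgrg1, an adhesion receptor gene, at 4.21, Ptgr1 at 4.12 and Lhfpl1 at 4.0 (SE up to 0.51, adjusted p up to 2.73e-06), Fbp1, Cdh17 and Cdhr2 at 3.91, 3.85 and 3.70 (SE up to 0.67, adjusted p up to 0.000141), and Xist at 4.06 (SE 1.23, adjusted p = 0.0174) and Igf2 at 3.74 (SE 0.98, adjusted p = 0.00652), measured at 2.25 and 2.39. With neighbouring-tissue covariates Fbp1 and Cdh17 did not pass. Without arrays with such tissue (1 asymptomatic node left) Cdh17 and Cdhr2 did not pass. Xist did not pass without asymptomatic mouse 2, 4 or 6 or lymphoma mouse 3, 4, 5 or 6 (adjusted p from 0.0587 to 0.689), nor Igf2 without asymptomatic mouse 4 or 6 or those 4 lymphoma mice (0.0576 to 0.723). Without lymphoma mouse 5 the values were 2.18 for Lhfpl1, 1.77 for Fbp1 and 2.04 for Cdh17, without lymphoma mouse 3 they were 1.98, 1.77 and 2.50, and without lymphoma mouse 2 Igf2 had 2.41.

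**Figure D3:**
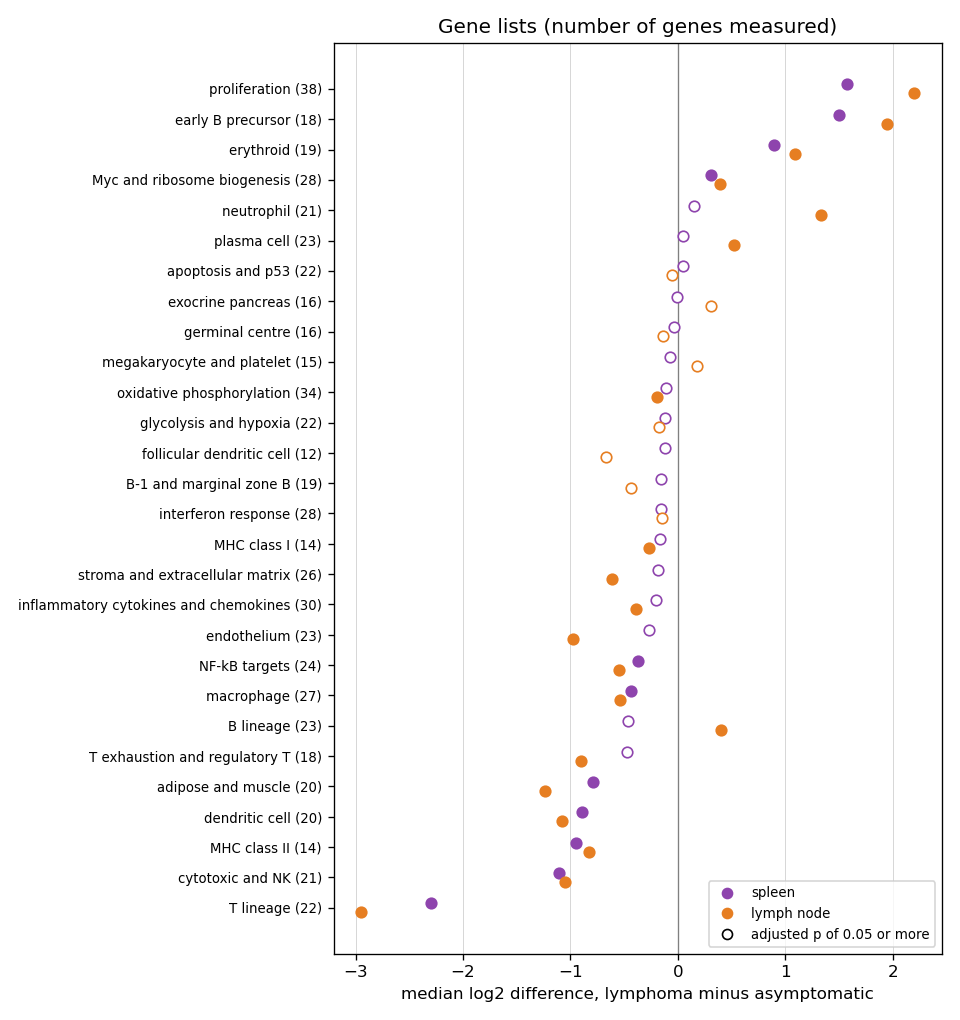
Median log2 difference between lymphoma and asymptomatic mice for 28 of the 30 gene lists in spleen (purple) and lymph node (orange), with the number of genes measured in parentheses. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation.

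Of the genes higher in spleen, 1349 were also higher in lymph node and 0 were lower, and of those lower in spleen, 1029 were also lower and 1 was higher. Independent lists would have shared 199 and 180, but the same mice gave both tissues. Blnk, Cd79b and Pou2af1 changed by 1.35, 1.13 and 0.93 more in lymph node than in spleen (SE up to 0.18, adjusted p up to 0.00325), and the B cell transcription factor Pax5 by 1.17 (SE 0.23, adjusted p = 0.0184). The change in Mzb1, Tnfrsf13b, Cd24a and Plac8 was higher by 1.63, 0.92, 1.76 and 1.80 (SE up to 0.33, adjusted p up to 0.0194). The 5 largest positive differences were those of S1pr3 at 2.58, Serpinb10 at 2.27, Asb2 at 2.26, Pla2g7 at 2.23 and the macrophage elastase gene Mmp12 at 2.02 (SE up to 0.55, adjusted p up to 0.043). The 5 most negative were those of Fabp4 at -2.77, Cyp1b1 at -1.98, Mfge8 at -1.90, Timp3 at -1.79 and Fscn1 at -1.74 (SE up to 0.54, adjusted p up to 0.0445). The chemokine genes Ccl22 and Cxcl10 had -1.55 and -1.34, the vessel genes Egfl7 and Tek -1.34 and -1.10, and Ubash3a -1.21, against 0.04 measured (SE up to 0.34, adjusted p up to 0.0383). In all, 114 genes differed between the tissues, 51 with the higher change in lymph node and 63 with the lower. The count was 795 with batch as a term, 29 and 425 within batches A and B, 182, 456 and 34 without asymptomatic mouse 6, 1 and 2, and 204 and 62 without lymphoma mouse 1 and 3. With neighbouring-tissue covariates it was 0, with 1297 genes at an unadjusted p under 0.05. Calls of 14 of the 23 genes named in this comparison, all but Asb2, Pla2g7, Timp3, Blnk, Cd79b, Pou2af1, Mzb1, Cd24a and Plac8, ended without some 1 mouse. They were 2, 13, 4, 1, 1 and 1 without asymptomatic mouse 1 to 6 and 4, 9, 3, 6 and 1 without lymphoma mouse 2 to 6 (adjusted p up to 0.168).

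As groups, 11 lists differed between the tissues by camera, and none passed with an estimated correlation. Of 23 B lineage genes, Blnk, Cd79b, Ebf1, Pax5, Pou2af1 and Vpreb3 were higher (10 adjusted over the list alone), with camera adjusted p = 9.09e-14, but adjusted p = 0.0816 with an estimated correlation. Of 23 endothelium genes, Egfl7 and Tek were lower (16 adjusted over the list alone), with camera adjusted p = 1.42e-15, but adjusted p = 0.206 with an estimated correlation. Mzb1 and Tnfrsf13b were higher among plasma cell genes, Ubash3a lower among T lineage genes (3 with Zap70 and Bcl11b adjusted over the list alone), Fabp4 lower among adipose and muscle genes and Cxcl10 lower among inflammatory genes (4 with Il12b, Il15 and Ccl5 lower, and Il1b and Ccl3 higher, adjusted over the list alone). These lists had camera adjusted p = 0.00164, 9.42e-09, 0.0028 and 0.00721, but 0.337, 0.333, 0.459 and 0.376 with an estimated correlation. For the neutrophil and proliferation lists, which were higher, and the T exhaustion, stroma and NF-kB lists, which were lower, 0 genes passed, with 11, 12, 10, 8 and 6 in that direction at an unadjusted p under 0.05. Adjusted over the list alone, the neutrophil genes Ly6g, Ltf, Ngp, Lcn2 and Chil3, the proliferation gene Aurkb, 8 T exhaustion genes, the stroma genes Lum, Ccl19 and Cxcl12 and the NF-kB target Tnip1 passed in that direction. Camera gave adjusted p = 1.22e-09, 3.31e-11, 2.76e-05, 5.09e-06 and 0.0277, but 0.337, 0.376, 0.337, 0.398 and 0.564 with an estimated correlation. The medians of fitted and measured differences had opposite signs for the plasma cell (0.24 and -0.03), T lineage (-0.62 and 0.44) and NF-kB (-0.12 and 0.12) lists, and in batch B the T lineage list passed the other way (0.87, adjusted p = 0.000315). The inflammatory list did not pass without asymptomatic mouse 2, 4 or 5 or lymphoma mouse 2, 4, 5 or 6 (0.0591 to 0.332), and the NF-kB list did not pass with any 1 of the 12 mice left out other than lymphoma mouse 3 (0.0523 to 0.967).

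Against their background strain, asymptomatic Tg26 mice had higher spleen levels of Mrc1, Hmox1, C1qc and C1qb. Mrc1, the mannose receptor gene, went from 6.09 ± 0.10 (SD, n = 3) in FVB/N to 8.44 ± 0.23 (SD, n = 6) in asymptomatic spleens, a fitted rise of 2.09 (SE 0.41, adjusted p = 0.0157). The heme oxygenase gene Hmox1 and the complement genes C1qc and C1qb rose by 2.05, 1.94 and 1.5 (SE up to 0.37, adjusted p up to 0.0189). The adhesion gene Vcam1 rose from 7.30 ± 0.19 (SD, n = 3) to 9.73 ± 0.22 (SD, n = 6), by 2.61 (SE 0.57, adjusted p = 0.0359). The junction gene Jam2 rose by 2.88 (SE 0.28, adjusted p = 1.4e-05), D17H6S56E-5 by 3.08, the heme synthesis gene Alas2 by 2.26 and the interferon-induced gene Rsad2 by 1.92 (largest SE 0.69, adjusted p = 0.0359 each), and Clec1b by 1.44 (SE 0.27, adjusted p = 0.0125). The NK receptor genes Klrb1b and Klra8 differed by -1.73 and -1.20 (SE up to 0.19, adjusted p up to 0.00129), and Ly6d by -1.49 (SE 0.21, adjusted p = 0.000962). The stress gene Atf3, Gdap10, Gla and the NF-kB inhibitor genes Tnfaip3 and Nfkbiz differed by -2.0, -1.75, -1.65, -1.31 and -0.82 (SE up to 0.39, adjusted p up to 0.0169), the clock gene Ciart by -2.29 (SE 0.47, adjusted p = 0.0221) and the chemokine gene Xcl1 by -0.68 (SE 0.16, adjusted p = 0.0499). In all, 123 of 19938 genes changed, 61 higher and 62 lower. The count was 24 with batch as a term, 10 within batch A, 2269 with array weights and 106 with mice paired by number. It was 252, 17 and 14 without FVB/N mouse 1, 2 and 3, and 47, 54 and 52 without asymptomatic mouse 1, 2 and 3. With mice paired by number Vcam1, Ciart and Xcl1 had adjusted p = 0.0623, 0.0595 and 0.096, and Xcl1 had 0.0542 with spleen and node of a mouse as a block. Only Jam2, Klrb1b, Klra8 and Ly6d passed without each mouse in turn. Without FVB/N mouse 3 the other 16 genes did not pass (adjusted p from 0.059 to 0.749), without FVB/N mouse 2 15 did not (to 0.597), and without asymptomatic mouse 1, 2, 3, 4 and 5 11, 7, 8, 4 and 2 did not (to 0.205). D17H6S56E-5 did not pass without FVB/N mouse 1 (0.0679), where Ciart and Xcl1 differed by -3.45 and -1.04, nor Xcl1 without asymptomatic mouse 6 (0.101).

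In spleen, 7 lists differed between asymptomatic and FVB/N mice by camera, and none passed with an estimated correlation. Of 27 macrophage genes, 7 rose (13 adjusted over the list alone). Of 24 NF-kB targets, Nfkbiz and Tnfaip3 fell (4 with Rel and Ccl3 adjusted over the list alone). Both lists had camera adjusted p = 3.49e-16 and 3.19e-07, but 0.229 each with an estimated correlation. Klra8 and Xcl1 fell among 21 cytotoxic and NK genes, and Alas2, Clec1b and Rsad2 rose as the only ones among 19 erythroid, 15 megakaryocyte and 28 interferon response genes, also adjusted over the list alone. Camera gave adjusted p = 0.0111, 0.0139, 0.000273 and 0.00015, but 0.968, 0.968, 0.686 and 0.968 with an estimated correlation. Of 21 neutrophil genes 0 passed, also adjusted over the list alone, with 3 higher at an unadjusted p under 0.05, and the list was higher with camera adjusted p = 0.0214, but adjusted p = 0.968 with an estimated correlation and adjusted p = 0.228 with mice paired by number. The erythroid median was 0.28 fitted and -0.05 measured. Without FVB/N mouse 2 or 3 the cytotoxic, neutrophil and erythroid lists did not pass (0.195 to 0.582), nor the cytotoxic list without asymptomatic mouse 1 (0.286), the neutrophil list without 2 or 4 or the erythroid list without 2 (0.0799 to 0.114).

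Of neighbouring-tissue genes in lymph node, Ucp1 and Pck1 were higher in asymptomatic than in FVB/N mice, and Odam was lower. Ucp1, the uncoupling protein of brown fat, was at 9.68 ± 2.71 (SD, n = 6) against 6.51 ± 2.10 (SD, n = 3), a fitted rise of 3.25 (SE 0.62, adjusted p = 0.0084). Cox8b, Pck1, Cidec, Plin1 and Fabp4, which are expressed in fat or muscle, rose by 2.93, 2.88, 2.56, 2.15 and 2.17 (SE up to 0.60, adjusted p up to 0.0127), and Cyp2e1 by 2.75 (SE 0.65, adjusted p = 0.0309). Odam, Prpmp5, Klk1b11, B4galnt2 and Klk1b22, among them salivary secretion genes, differed by -2.66, -2.63, -2.39, -2.13 and -1.96 (SE up to 0.60, adjusted p up to 0.0492). The respiratory chain genes Ndufa8, Sdhd and Uqcrfs1 rose by 0.74, 0.69 and 0.60 (SE up to 0.15, adjusted p up to 0.0202). The class II genes H2-Ea and H2-Aa rose by 2.84 and 1.07, the chemokine gene Ccl8 by 1.87, Clec1b by 1.56, Bnip3 by 0.89 and Cldn5 by 0.81 (SE up to 0.62, adjusted p up to 0.0468), while Ly6d and Klra8 differed by -1.22 and -0.74 (SE up to 0.23, adjusted p up to 0.0471). In all, 386 genes changed, 268 higher and 118 lower. With quantile normalization the split was 103 higher and 74 lower, and with median centring it was 110 higher and 158 lower. The count was 8 with batch as a term, 3 within batch A, and 3 with neighbouring-tissue covariates, where no named gene outside the covariate lists passed. It was 217, 782, 212 and 76 without asymptomatic mouse 4, 1, 2 and 3 and 40 without FVB/N mouse 2. With mice paired by number it was 165, and Cox8b, Cyp2e1, Prpmp5, Klk1b11, B4galnt2, Klk1b22, Klra8, Cldn5, Ccl8, H2-Aa, Sdhd and Bnip3 did not pass (adjusted p from 0.0517 to 0.102). With spleen and node of a mouse as a block Klk1b22, Klra8 and Cldn5 had adjusted p = 0.0601, 0.0605 and 0.0633. Only Pck1 and Cidec passed without each mouse in turn. The number of named genes that did not pass was 5, 18 and 9 without FVB/N mouse 1, 2 and 3 (adjusted p to 0.546), and 2, 11, 15, 6, 3 and 8 without asymptomatic mouse 1 to 6 (to 0.222). Without FVB/N mouse 1, Odam, Prpmp5, Klk1b11, B4galnt2 and Klk1b22 differed by -4.13, -4.14, -3.67, -3.37 and -3.12, and without asymptomatic mouse 1 Klk1b11 and Klk1b22 by -3.60 and -3.05.

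In lymph node, 11 lists differed between asymptomatic and FVB/N mice by camera, and none passed with an estimated correlation. Of 20 adipose and muscle genes, 9 rose (10 adjusted over the list alone). Ndufa8, Sdhd and Uqcrfs1 rose among 34 oxidative phosphorylation genes (20 adjusted over the list alone). Both lists had camera adjusted p = 1.78e-10 and 1.01e-13, but 0.203 each with an estimated correlation. With neighbouring-tissue covariates, of which the adipose list is 1, the oxidative phosphorylation list was lower, with a median of -0.30 and adjusted p = 3.76e-07. The proliferation (0.04, adjusted p = 0.907) and glycolysis (-0.22, 0.065) lists turned as well. Cldn5 rose among 23 endothelium genes (5 with Tek, Tie1, Flt4 and Egfl7 adjusted over the list alone), Clec1b among 15 megakaryocyte genes, H2-Aa among 14 class II genes (3 with H2-Eb1 and Ctss), Ccl8 among 30 inflammatory genes and Bnip3 among 22 glycolysis genes (3 with Pfkl and Pgam1). These lists had camera adjusted p = 5.9e-07, 0.00661, 0.000579, 0.0286 and 0.0149, but adjusted p = 0.401, 0.595, 0.253, 0.543 and 0.401 with an estimated correlation. In the macrophage and stroma lists, which were higher, and the proliferation and Myc lists, which were lower, 0 genes passed, with 13, 7, 4 and 10 in that direction at an unadjusted p under 0.05, and Nop56, Nolc1, Dkc1 and Polr1b of the Myc list passed adjusted over the list alone. Camera gave adjusted p = 2.13e-07, 0.000523, 0.000523 and 6.03e-07, but 0.401, 0.631, 0.76 and 0.401 with an estimated correlation. With mice paired by number the inflammatory and glycolysis lists had adjusted p = 0.0842 and 0.0863. Without asymptomatic mouse 4 the megakaryocyte, stroma, inflammatory and class II lists did not pass (0.0801 to 0.324), and the megakaryocyte list did not without asymptomatic mouse 1 (0.0945). Without FVB/N mouse 1 the megakaryocyte, stroma, endothelium, Myc, inflammatory and class II lists did not pass (0.0548 to 0.601). Without FVB/N mouse 2 the stroma, endothelium, inflammatory and glycolysis lists did not (0.0678 to 0.913), and the glycolysis list did not without FVB/N mouse 3 (0.185) or asymptomatic mouse 3 (0.12). The proliferation list did not pass without asymptomatic mouse 5 (0.0531), and the inflammatory list did not without asymptomatic mouse 2, 3, 5 or 6 (0.0531 to 0.455).

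Against FVB/N mice, in spleen, Drc7, Igll1, Cd93 and Myb rose by 4.94, 4.55, 3.46 and 2.99, and Ptgr1 by 4.19 (SE up to 0.43, adjusted p up to 7.7e-07). Dapl1, Ly6d, Themis and Cd3d differed by -4.56, -3.22, -2.91 and -2.74 (SE up to 0.42, adjusted p up to 1.01e-06). The mitotic genes Bub1b and Ccnb2 rose by 2.44 and 2.27, the cytotoxic and NK cell genes Xcl1, Ctsw and Ncr1 differed by -1.91, -1.92 and -2.39, and Traf1, Nfkb2 and Tnip1 by -1.68, -1.08 and -0.76 (SE of these 8 genes up to 0.28, adjusted p up to 7.81e-05). In lymph node, Drc7, Igll1, Adgrg1, Cd93, Myb and Vpreb1, another surrogate light chain gene, rose by 5.39, 5.25, 4.84, 4.18, 3.35 and 3.02 (SE up to 0.47, adjusted p up to 2.2e-07). Dapl1, Cd3g, Cd3d, Themis and the T cell kinase gene Zap70 differed by -4.65, -3.55, -3.46, -3.45 and -2.57 (SE up to 0.55, adjusted p up to 6.18e-05). In all, 2462 genes changed in spleen, 1415 higher and 1047 lower, and 3304 in lymph node, 1713 higher and 1591 lower. With batch as a term the counts were 3018 and 4485, and within batch A 3177 and 3575. The spleen count was 4495 without lymphoma mouse 5 and 1605 without FVB/N mouse 3.

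By camera, 13 lists differed from FVB/N in spleen and 16 in lymph node, of which 5 and 2 passed with an estimated correlation and are described, with 1 that ran against the change from asymptomatic mice. In spleen, 13 of 18 early B precursor genes rose and Flt3 fell (13, and 2 with Lef1, adjusted over the list alone), 36 of 38 proliferation genes rose (36 adjusted over the list alone), and 19 of 22 T lineage genes (20), 15 of 21 cytotoxic and NK genes (16) and 15 of 24 NF-kB targets (18, with Tnfaip2 and Bcl2l1 higher) fell. Their camera adjusted p were 3.43e-13, 3.02e-40, 1.57e-28, 2.1e-12 and 7.89e-12, or adjusted p = 0.00485, 0.0269, 0.00941, 0.0233 and 0.0233 with an estimated correlation. In lymph node, 12 early B precursor genes rose and Flt3 and Lef1 fell (the same adjusted over the list alone), and 20 T lineage genes fell (21). Camera adjusted p were 1.03e-11 and 8.03e-31, or 0.00651 each with an estimated correlation. In lymph node Cox5a, Ndufb8, Ndufs8 and Sdhd of 34 oxidative phosphorylation genes rose, also adjusted over the list alone, with camera adjusted p = 0.0336 upward, but adjusted p = 0.594 with an estimated correlation and adjusted p = 0.805 without surrogate variables. This list was lower than in asymptomatic mice, and it did not pass without lymphoma mouse 1, 2 or 6 or FVB/N mouse 3 (0.105 to 0.92). Lists that passed against asymptomatic mice but not FVB/N were macrophage in spleen (adjusted p = 0.0715) and macrophage, adipose, class II, Myc and inflammatory in lymph node (0.783, 0.514, 0.13, 0.13 and 0.083). Xist and Igf2 had 5.67 and 4.58 in spleen and 5.76 and 5.06 in lymph node (SE up to 1.47, adjusted p up to 0.00769), and Eif2s3y, Kdm5d and Uty differed by -5.24, -3.71 and -3.67 and by -4.78, -4.41 and -3.53 (SE up to 1.18, adjusted p up to 0.00608). Measured means differed less, by 1.93, 2.25, 2.34 and 2.73 for Xist and Igf2 and between -2.25 and -1.65 for the Y genes. None of these 10 calls passed without surrogate variables or without lymphoma mouse 5, where adjusted p lay between 0.217 and 0.835 in spleen and between 0.114 and 0.928 in lymph node. Without lymphoma mouse 3, Xist and Igf2 in both tissues and Eif2s3y and Uty in lymph node did not pass (0.0624 to 0.646), while Eif2s3y, Kdm5d and Uty in spleen differed by -1.98, -1.70 and -1.36 and Kdm5d in lymph node by -2.48. Without lymphoma mouse 4, Xist and Igf2 in spleen and Xist, Eif2s3y and Uty in lymph node did not pass (0.0622 to 0.109). Igf2 in spleen did not pass without lymphoma mouse 2 (0.0723) or FVB/N mouse 2 (0.084) and had 2.84 in lymph node without lymphoma mouse 2, and Xist and Eif2s3y in lymph node did not pass without FVB/N mouse 1 (0.108 and 0.0645).

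For 12 probe sets of immunoglobulin kappa variable segments, deviations from the group mean in spleen correlated with those in the node of the same mouse at 0.437 on average in lymphoma mice, against -0.086 between different mice. The difference was 0.523 (720 pairings, exact two-sided permutation test, p = 0.0153, n = 6 mice). Same-mouse correlations ran from -0.1 to 0.852, and 3 of 6 spleens correlated best with their own node. Asymptomatic mice gave 0.362 and -0.073, a difference of 0.435 (exact two-sided permutation test, p = 0.0153). Segments are not independent replicates. In lymphoma mice the test gave p = 0.0556 with pairings kept within batches, p = 0.05 without mouse 1, p = 0.0583 without mouse 2, and a difference of 0.357 with p = 0.14 without the dimmest segments, each by the exact test.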

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

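Genes and number-pair splits in this part were chosen after results were seen. Rag1, Igll1, H2-Ea and the erythroid list each stood apart in 1 asymptomatic mouse. In the lymph node of asymptomatic mouse 4, Rag1 was at 7.59 (next highest 5.73), Igll1 at 8.82 (6.73) and the mean of the early B precursor list at 7.91 (7.56), below the levels with lymphoma for Rag1 and Igll1. In asymptomatic mouse 5, H2-Ea was low in lymph node at 8.75 (next lowest 11.32) and in spleen at 10.30 (12.21), and D17H6S56E-5 was low in spleen at 6.93 (9.52). The lymph node of asymptomatic mouse 6 was high in erythroid genes at 9.05 (6.52), megakaryocyte genes at 8.33 (7.26) and B-1 and marginal zone genes at 8.29 (8.19). That of asymptomatic mouse 1 was low in macrophage genes at 7.62 (9.31) and in Mrc1 at 6.44 (9.75), and high in interferon response genes at 8.45 (7.98) and Kdm5d at 8.72 (8.25). Among lymphoma spleens, that of mouse 4 was low in follicular dendritic cell genes at 7.16 (7.60) and that of mouse 1 high in exocrine pancreas genes at 6.74 (6.07). By Dixon's limit 1 group in 20 gives such a value by chance. That is 6 of 120 list groups (8 found) and 3.4 of 68 chosen gene groups (7 found). The cause was not tested.

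Of probe sets with no symbol, which were not named, 1060 changed with lymphoma in spleen and 931 in lymph node (8.73% and 7.67%), and of those with several symbols, 392 and 341 (24.2% and 21%).

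Counts of changed genes were compared with those of other splits of the same mice into groups of the same sizes. For lymphoma against asymptomatic mice, 100 of 462 splits were run. Only the real one gave as many genes in spleen (3156, next 196), lymph node (4800, next 290) and between tissues (114, next 3). Chance is thus unlikely, but the split that followed batch, outside this draw, gave more in spleen (5463) and 3868 in lymph node. With batch as a term the real groups gave 4008 and 6537. For lymphoma against FVB/N, 1 of 84 gave as many in spleen (2462, next 1122) and 1 of 84 in lymph node (3304, next 549). Chance is unlikely. For asymptomatic against FVB/N in spleen, 2 of 84 did (123, next 257, the split that followed batch, with 24 for the real groups with batch as a term). In lymph node 9 of 84 did (386, highest 2335), so chance cannot be excluded, and a highest value several times the real one points to another structure in these samples. With all 3 number pairs parted, 8 splits remain, too few for a share under 0.05, and only the real one gave as many (next 1 in spleen and 301 in lymph node).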

How the results depend on the processing

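Of 35 settings, 15 left out 1 mouse each and 4 were added after the results were seen. The 4 were Eif2s3y minus Xist as covariate, no lymphoma mice 3 and 5, no neighbouring-tissue arrays, and neighbouring-tissue lists with batch replacing surrogate variables. Against asymptomatic mice, where 32 were run, Rag1, Igll1, Drc7 and Cd3g changed in both tissues in every one. Of the genes named, 47 of 65 passed in all settings for lymphoma against asymptomatic spleen, 47 of 81 in lymph node, 17 of 22 and 11 of 16 against FVB/N, 1 of 20 and 0 of 23 for asymptomatic against FVB/N and 0 of 23 for the difference between tissues. Of the list calls, 7 of 11, 10 of 20, 5 of 5, 2 of 3, 3 of 7, 0 of 11 and 2 of 11 did, where against FVB/N only the 5 of 13 and 3 of 16 described for lymphoma were run. Of 68 list and 250 gene calls, 23 and 91 ended with neighbouring-tissue covariates (4 and 14 of them in the covariate lists, which this cannot test), 16 and 84 without those arrays, 20 and 72 without surrogate variables, 22 and 69 with 1, 19 and 70 with batch as a term, 20 and 66 with batch and mouse, 21 and 88 in batch A, 11 and 70 with all probe sets, 12 and 56 with the Eif2s3y covariate (7 of these genes Xist or Eif2s3y, its parts), 16 and 42 without lymphoma mice 3 and 5, and 10 and 7 without the spleen array of lymphoma mouse 4. Of fewer calls they were 12 of 42 and 46 of 169 in batch B, 15 of 57 and 44 of 227 with 1 tissue only and 13 of 68 and 6 of 226 without the lowest genes. With quantile normalization they were 2 and 16, with median centring 7 and 27, with array weights 7 and 9, with a trended prior 0 and 5, with mice as blocks 0 and 4, with mice paired by number 5 and 22. All-gene median differences were at most 0.025 in size with scalings and 0.098 elsewhere. Ddx3y minus Xist could not be used, since no single-symbol probe set reads Ddx3y, nor heavy-chain segments alone, since all 12 segments are kappa.

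Counts that moved over 1.5-fold in spleen with lymphoma were 6595 with the arrays of that tissue only, 1678 in batch B and 5921 with all probe sets, and in lymph node 2966 with neighbouring-tissue covariates and 2353 without those arrays. Against FVB/N, lymphoma spleens gave 5110 with that tissue only, 3728 with all probe sets, 4161 with array weights and 3994 without lymphoma mice 3 and 5, and nodes gave 5043 with 1 surrogate variable. Asymptomatic against FVB/N spleens gave 23 with no or 1 surrogate variable, 24 with batch, 23 with batch and mouse, 10 in batch A, 75 with all probe sets, 2269 with array weights, 80 without lymphoma mice 3 and 5, 30 with neighbouring-tissue covariates and 67 without those arrays. Nodes gave 13, 6, 8, 6 and 3 in the same first 5 settings, 165 paired by number, 3 with that tissue only, 177 with quantile normalization, 9 with all probe sets, 243 with array weights, 847 without the spleen array of lymphoma mouse 4, 60 with the Eif2s3y covariate, and 3 and 8 in the 2 neighbouring-tissue settings. The difference between tissues gave 596, 560, 795, 1384 and 29 in those first 5 settings, 425 in batch B, 267 without the lowest genes, 53 with all probe sets, 30 with the Eif2s3y covariate, 0 with neighbouring-tissue covariates (limma, 1297 at an unadjusted p under 0.05) and 45 without those arrays. With 1 mouse left out, counts ran from 2304 to 5087 and 3184 to 5007 (lymphoma against asymptomatic), 14 to 252 and 40 to 782 (asymptomatic against FVB/N), 1605 to 4495 and 2292 to 4104 (lymphoma against FVB/N) and 34 to 456 (between tissues). The segment difference of 0.523 was 0.357 without the dimmest segments and up to 0.682 without lymphoma mouse 4.

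List medians that turned or fell to 0.00, or turned by camera, with lymphoma in spleen were macrophage 0.22 in batch A, erythroid -0.08 in batch B, and adipose -0.04 with no or 1 surrogate variable, batch, or batch and mouse, -0.05 in batch A and -0.02 with neighbouring-tissue covariates. In lymph node they were B lineage -0.19 with no surrogate variables, batch, or batch and mouse, -0.06 with 1, -0.34 in batch B, -0.03 with that tissue only, -0.07 without lymphoma mice 3 and 5, -0.24 and -0.44 in the neighbouring-tissue settings and -0.04 without lymphoma mouse 3, plasma cell -0.03 in the same first 3, -0.14 with 1 and -0.10 and -0.09 in batches A and B, macrophage 0.02 without neighbouring-tissue arrays, erythroid -0.39 in the same 3, -0.20 with 1 and -0.71 in batch B, adipose 0.17 with neighbouring-tissue covariates, and oxidative phosphorylation 0.06 with median centring or without lymphoma mice 3 and 5, 0.56 and 0.18 in the neighbouring-tissue settings and 0.08, 0.06 and 0.03 without asymptomatic mouse 6 or lymphoma mouse 5 or 3 (lowest -0.40 without asymptomatic mouse 1). For asymptomatic against FVB/N they were erythroid -0.15 and -0.05 in spleen with 1 or no surrogate variable and cytotoxic 0.00 without FVB/N mouse 2, and in lymph node class II 0.00 in batch A, adipose 0.04, proliferation 0.04, oxidative phosphorylation -0.30 and glycolysis -0.22 with neighbouring-tissue covariates, proliferation 0.05, inflammatory 0.18, oxidative phosphorylation 0.08 and glycolysis 0.09 without those arrays (1 node per group left) and inflammatory 0.11 without FVB/N mouse 2 (highest 0.42 without mouse 3). Against FVB/N nodes, oxidative phosphorylation with lymphoma turned by camera with no surrogate variables (0.06) or 1 (0.04), batch or batch and mouse (0.00), in batch A (-0.05) and without lymphoma mouse 2 (0.05, highest 0.56 without mouse 5). Between tissues they were plasma cell -0.03 with none, batch, or batch and mouse, -0.07 with 1 surrogate variable and -0.10 in batch A, T lineage 0.44 with none, batch, or batch and mouse, 0.23 with 1 and 0.87 in batch B, proliferation -0.01 with 1, adipose 0.11 with neighbouring-tissue covariates, and NF-kB 0.12 with none, batch, or batch and mouse, 0.06 with 1, and 0.19 and 0.05 in batches A and B. The adipose medians with neighbouring-tissue covariates are no test, since the list is 1 of them.

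Fitted gene values that turned in spleen, against asymptomatic mice, were Xist -0.10, -0.05 and -0.25 and Uty 0.21 and 0.20 with the Eif2s3y covariate, without lymphoma mice 3 and 5 and, for Xist, without neighbouring-tissue arrays. Without mice 3 and 5, Igf2 had -0.39, Il1r2 -0.03, Scin -0.30 and Eif2s3y 0.11, and without neighbouring-tissue arrays Igf2 had -0.48, Scin -0.24 and Eif2s3y 0.21. In lymph node Xist had -0.68 and Igf2 -0.58 without those arrays, and Sdha 0.01 with the covariates. Against FVB/N, in the same 3 settings, spleens gave Xist -0.18, -0.13 and -0.62 and Igf2 -0.39, -0.91 and -1.21, with Eif2s3y 0.25 in the last and Igf2 -0.24 without lymphoma mouse 5 (highest 5.6 without mouse 1), and nodes gave Eif2s3y 0.11, 0.17 and 0.80, Igf2 -0.09 and -0.95 in the last 2 and Xist -0.34 in the last. For asymptomatic against FVB/N nodes, Cyp2e1 had -0.18, Odam 0.63, Klk1b11 0.26, B4galnt2 0.25 and Klk1b22 0.10 without neighbouring-tissue arrays, which left 1 node per group, so these signs rest on single arrays, and Ndufa8 -0.05, Sdhd -0.12 and Bnip3 -0.28 with the covariates. Between tissues Ubash3a had 0.04 with no surrogate variables, batch, or batch and mouse and 0.57 in batch B. No other named call turned. Of these 41 fitted values, 3 are no test, as the Eif2s3y covariate is made of Xist and Eif2s3y. Of the other 38, 26 ran against the measured difference on the same arrays, 13 of 17 without neighbouring-tissue arrays. There the measured means kept Xist 1.22 to 2.01 and Igf2 2.17 to 2.47 higher with lymphoma. Without mice 3 and 5 Igf2 was 0.79 to 1.38 higher, so those turns came from the surrogate variables. So did the excess of reported over measured sizes for Xist and Igf2.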

Other observations

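The sex genes, the neighbours of Drc7, the genes shared by Tg26 tissues, the T lineage test and the NK test were looked at only after the results were seen. Igf2 was high in both tissues of lymphoma mice 3, 4 and 5, between 10.54 and 12.78, against 5.55 to 8.05 elsewhere. Xist, expressed from the inactive X chromosome of females, was at 11.37 and 11.93 and at 11.06 and 10.91 in spleen and node of lymphoma mice 3 and 5, where the Y gene Eif2s3y was between 3.59 and 4.06. Lymphoma mouse 1 had low Kdm5d (6.30 and 5.78) with Eif2s3y at 9.77 and 9.40. The cause was not tested.

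Drc7 rose with its neighbours Adgrg1, by 3.36 in spleen and 4.21 in lymph node (SE up to 0.24, adjusted p up to 4.23e-10), and Adgrg3, by 2.12 and 2.65 (SE up to 0.28, adjusted p up to 2.28e-06). Kifc3 differed by -0.36 and -0.56 (SE up to 0.13, adjusted p up to 0.0353). The neighbours Polr2c, Dok4, Ccdc102a, Cngb1, Tepp, Zfp319 and Usb1 did not change.

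Tek and Cdh5 were among 17 endothelium genes lower in nodes with lymphoma, and 2 explanations were tested. Neighbouring organs taken with tumour-free nodes could carry vessels, and with batch and the 3 tissue lists in the fit the list differed by -1.04 (SE 0.41), against -1.57 with batch alone and -0.98 in the reported fit. This lay over 2 SE from 0 but not over 2 SE beyond -0.49, so it stays open. That bound was set before this test, but from the reported -0.98. A lower share of node tissue as a whole would need T lineage genes to be lower too, and they were, at -2.95. That was known when the test was chosen, and with batch and the tissue lists they fell further than endothelium genes (difference -2.05, SE 0.77), so this stays open too.

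Ucp1 and Odam, which differed between asymptomatic and FVB/N nodes, are in the lists that mark tissue taken with the node. Of the 386 changed genes, 15 are in these lists. With them and batch in the fit, 0.518% (2) passed, against 2.07% (8) with batch alone. A share under 10% was set beforehand for this source, but batch alone met it too, so for genes outside the lists this stays open.

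In a fit with batch and no surrogate variables, 10 genes were higher and 6 lower in both tissues of asymptomatic than of FVB/N mice (unadjusted p limit 0.001). Independent tissues would give 0.29, but the same mice gave both. Higher were Abitram, AI506816, Clec1b, D17H6S56E-5, Hcrtr2, Klra3, Lipo3, Rab6b, Tatdn3 and Tmem245, and lower were Ahsa2, Atp6v1d, Chordc1, Hsph1, Klra8 and Klrb1b. Stretches of another strain's genome could set such genes, and 7 pairs lay within 2 Mb, as many as in 0 of 10000 random gene sets, but with receptor clusters taken as 1 only Abitram and Tmem245 did, at a share of 0.202, so this stays open. A lower share of NK cells would lower all the NK receptor genes, but Klra3 was higher (1) while Klra8 and Klrb1b were lower (2). As 1 gene decides nothing, and the cytotoxic and NK list was lower in spleen (camera adjusted p = 0.0111, but adjusted p = 0.968 with an estimated correlation), this stays open.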
